A study of Caenorhabditis elegans with 2 samples.

How the data were processed

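UNC-62 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L4 larvae of *Caenorhabditis elegans*. UNC-62 is a TALE-class homeodomain transcription factor of the Meis and Homothorax family. Per the labels, the worms were of strain OP600, which lacks normal unc-119 function and carries an integrated transgene with UNC-62 fused at its C terminus to a tag with TY1, EGFP and FLAG sequences, together with a rescuing unc-119 copy. The labels name unc-62 as the antibody target and do not say whether the antibody recognised the protein or the tag. Both samples are of a single group with 2 biological replicates of mixed-sex worms, fragmented by sonication per the labels. There was no second stage, genotype or treatment, so no comparison between groups was possible. The control library was not analysed here.

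The authors deposited peak lists in the narrowPeak layout. Per the file headers of the accompanying read-me texts, each replicate's list was derived from that replicate's alignments and a control, a further list from the alignments of both replicates pooled with a control, and a short list, named for the irreproducible discovery rate (IDR), from the lists of the replicates and the pool. Each kind of list exists for builds ce11 and ce10. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited signal value of each region was made by the authors against a control on a scale that is not given in the sources used here, and that differed between lists, so it was used to rank regions within a list, to correlate ranks and log2 values across peaks, and, in the closing section, to compare the log2 ratio of replicate 2 to replicate 1 between sets of peaks, where a constant factor between the lists cancels. The deposited lists also hold the −log10 of each region's q-value, which was the same for every region of the IDR list and therefore did not rank its peaks. The lists of single replicates and of the pool are unthresholded and contain background regions as input to the IDR step. They hold no read counts, so the sequencing depth is unknown and no interval that needs reads is given. Signal tracks were not used here.

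The ce11 IDR list, called the thresholded peaks, was the peak set of record. Coordinates are 1-based positions in ce11, and genes and sequence were taken from the WBcel235 assembly with Ensembl release 115, with which no ce11 coordinate lay past a chromosome end. Symbols of mitochondrial genes were taken from RefSeq by position on the same assembly. Lists for ce10 were used only for counts, overlap within that build and the share on X, for which the expectation used WBcel235 lengths. Nothing was converted between builds.

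A peak was counted as found in a replicate where it shared at least 1 bp with a region of that replicate's list, and as highly ranked there where that region was among as many of the highest regions as there were thresholded peaks. Chance values came from a permutation of positions. Peaks kept their own widths or, for overlap with the replicate lists, took the median width of the peaks on their chromosome. They were placed at random on their own chromosomes 1000 times. The smallest two-sided p this allows is 0.002. A promoter was the interval from 1000 bp upstream to 500 bp downstream of the start of any protein-coding transcript. Summits were assigned in the order promoter, 5′ UTR, coding exon, 3′ UTR, intron, non-coding RNA gene and intergenic, and were also tested for lying within 500 bp of a tRNA, snRNA, snoRNA, miRNA or rRNA gene. The share on X was tested by an exact two-sided binomial test against nuclear genome length. Sequence words were searched on either strand within 100 bp of the summit and compared by Fisher's exact test, two-sided, with 10 windows per peak matched on promoter class and on GC content within 2 percentage points. The 10 words included 2 controls, TTTCAGA and GACAGT, the latter being TGACAG written backwards. For 19 gene lists, members with a summit in a promoter window were compared with all other protein-coding genes by Fisher's exact test, two-sided. The heterochronic list, which holds miRNA genes, was compared with all annotated genes, with miRNA symbols taken from RefSeq for genes of the same start and end. An earlier form of this test had left its miRNA genes unmatched, and this was corrected after the results had been seen. The intestine, epidermis and heat shock lists each had 29 of 30 symbols in the annotation. P-values were adjusted by Benjamini-Hochberg within the 10 words, the 19 lists, the 7 annotation classes and the 5 RNA classes. Correlations of log2 signal across peaks carry p-values from 100000 permutations, and peaks are not independent replicates. Shares of peaks carry 95% Wilson intervals, which cover only the counting of peaks.

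These designs, the gene lists, the words and the alternatives were fixed before the data were examined, except for 2 peak sets that were added after seeing the data, namely the nuclear peaks alone and the 1000 highest nuclear regions of the pooled list. The alternatives fixed then were the ce10 lists, the thresholded peaks with signal at or above the median, other overlap rules, promoter windows, word windows and backgrounds, assignment to the nearest gene start within 5000 bp, and each replicate's highest regions in place of the thresholded peaks. The genes named were those at the 20 peaks of highest signal (the promoter's gene, or otherwise the nearest protein-coding start), up to 4 members of each list with a peak at the promoter, and unc-62, ceh-20, ceh-40, lin-39, mab-5, egl-5, ceh-13, vit-2, vit-5 and unc-119 whatever their values. Others are said to have been chosen after their values were seen.

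The comparisons were tested on simulated data of 197 peaks, with 40 sets for each case. Simulated peaks were placed at random on nuclear chromosomes by length, with no mitochondrial peaks and no clustering built in. Without an effect, the promoter test called 0 sets, the X test 1, the TGACAG test 3 and the gene list test 0 of 40. With 40 summits moved to promoters, 40 peaks moved to X, 30 summits moved near TGACAG or 6 ribosomal protein promoters added, each test called 40 of 40 sets. The sets thus check the tests under their own assumptions and for effects of these sizes only. The 6 planted ribosomal protein genes exceed the 4 observed, so power at the observed size was not assessed for gene lists. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and sequences were compared with BLAST 2.17.0.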

Results

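UNC-62 occupancy was profiled in whole L4 worms, in 2 biological replicates of a single tagged strain. The thresholded list held 197 peaks, of which 176 lay on nuclear chromosomes and 21 on the mitochondrial genome. Most peaks were 416 bp wide. The unthresholded lists held 18114 regions for replicate 1, 20477 for replicate 2 and 4849 for the pooled replicates, of which 1521, 604 and 352 had a q-value of 0.05 or less. The thresholded peaks were exactly the 197 regions of highest signal in the pooled list. Signal values, the authors' own, ran from 20.6 to 536 with a median of 26.2. The depth behind them is unknown.

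The strongest nuclear peaks lay beside genes of varied function, and 6 of the 9 nuclear peaks among the 20 highest contained TGACAG, the core word of Meis-class factors. The highest (chromosome II, 12518824 to 12519239) had a signal of 103 and its summit 173 bp upstream of srh-70, a predicted chemoreceptor gene, and within 500 bp of snoRNA and miRNA genes. It ranked 2 in replicate 1 and 9 in replicate 2. The next lay between genes on chromosome I (13337107 to 13337522, signal 85.5), 1169 bp upstream of casc-3, and ranked 1 and 17. A peak of signal 80.9 lay in an intron of fbxl-5 (chromosome V, 7744067 to 7744482) and ranked 4 and 15. All 3 contained TGACAG, as did promoter peaks at tmem-184 (X, 14706908 to 14707323, signal 57.1), nspc-17 (X, 14525706 to 14526121, signal 56.7) and ttr-45 (IV, 13253854 to 13254269, signal 54.98), the last of these a transthyretin-related gene. The other nuclear peaks among the 20 highest lacked the word. They lay in an intron of mom-1 with cest-16 as the nearest start (X, 6296429 to 6296844, signal 64.9), 1354 bp downstream of the start of F55G7.5 (X, 11937364 to 11937779, signal 52.7) and 6059 bp upstream of K02D3.1 (X, 13700640 to 13701055, signal 52.4).

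Mitochondrial DNA supplied the other 11 of the 20 highest peaks, including all of the highest 5. They lay at CYTB, ND5, ND2, COX3, ATP6, COX2 and COX1, which encode subunits of the respiratory chain and of ATP synthase, and the highest, at CYTB (4628 to 4877), had a signal of 536. The mitochondrial genome made up 0.0138% of the assembly and held 10.7% of the peaks, which covered 49.8% of its 13794 bp. The replicates differed here. Replicate 2 listed 25 mitochondrial regions, ranked from 1 to 91 and covering 61.3% of the mitochondrial genome, whereas replicate 1 listed 1, at rank 2518 with a signal of 4.59. Some results below are therefore also given for nuclear peaks alone, a peak set chosen after seeing the data.

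Because the design holds replicates of a single condition, the comparison it implies is between them. The nuclear peaks were found in both lists nearly throughout, but within this selected set their order by signal was only weakly shared. Of the 197 peaks, 173 (87.8%, 95% interval 82.5 to 91.7) overlapped a region in both replicates, against 3.77% by random placement (permutation p = 0.002, the smallest the 1000 placements allow). The thresholded list was itself derived from the lists of the replicates and the pool, so overlap beyond random placement was given by that selection, and these shares describe the list rather than test it. All 197 were in the list of replicate 2. Of the 176 nuclear peaks, 172 (97.7%) were in both. The lists are long, and the share among the 197 highest regions of both replicates was lower, at 68 peaks (34.5%, interval 28.2 to 41.4), with 0.0543% by random placement (permutation p = 0.002). Replicate 1 ranked 56.9% of the peaks that high, and replicate 2 ranked 70.6%. No mitochondrial region was among the highest of replicate 1. Of the 176 nuclear peaks, 68 (38.6%) were that high in both. The share was 59.6% among the 99 peaks with signal at or above the median, and the 20 highest nuclear peaks all ranked that high in both.

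Across the 173 peaks found in both, which are not independent replicates, log2 signal gave Spearman's rho of 0.12 (permutation p = 0.112) and Pearson's r of 0.22 (permutation p = 0.00435). Across the 172 nuclear peaks, again not independent replicates, the values were 0.14 (permutation p = 0.0723) and 0.24 (permutation p = 0.00169). These peaks were selected on pooled signal, which narrows the range. It can also lower the correlation, because a peak low in either replicate had to be high in the other to be kept. These values therefore do not measure how well the replicates agree beyond the selected peaks. Across the 2794 nuclear regions of the pooled list found in both lists, likewise not replicates, rho was 0.19 and r 0.34, each with permutation p = 1e-05, the smallest obtainable.

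**Figure D1:**
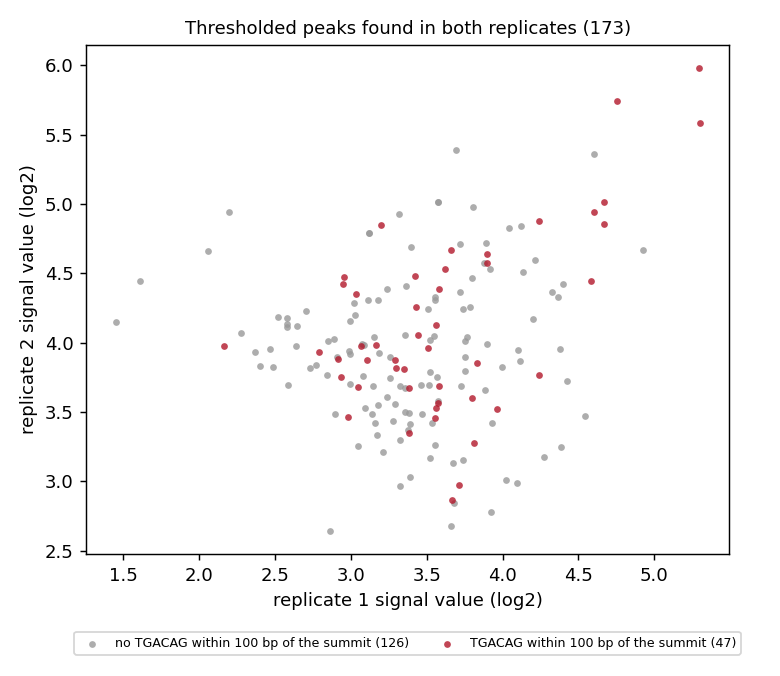
Signal values in replicate 1 (horizontal axis, log2) and replicate 2 (vertical axis, log2) of the 173 thresholded peaks found in both replicate lists, each point a peak, with the 47 that contain TGACAG in red. The peaks at srh-70, casc-3 and fbxl-5 stand at the upper right, and over all points Spearman's rho is 0.12.

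UNC-62 peaks were more frequent on the X chromosome than its length gives. X held 56 of the 176 nuclear peaks (31.8%, interval 25.4 to 39.0), against 17.7% of nuclear length (exact binomial p = 6.22e-06) and 13.7% of protein-coding genes (exact binomial p = 7.15e-10). The share was 32.0% among the highest regions of replicate 1 and 29.1% in replicate 2, and 29.6% in the ce10 list. It was 21.1% (interval 19.96 to 22.3) among the pooled regions ranked after the thresholded peaks. Chromosome I held 15 peaks (8.52% against 15.03% of length) and chromosome V 24 (13.6% against 20.9%), differences that were not tested.

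**Figure D2:**
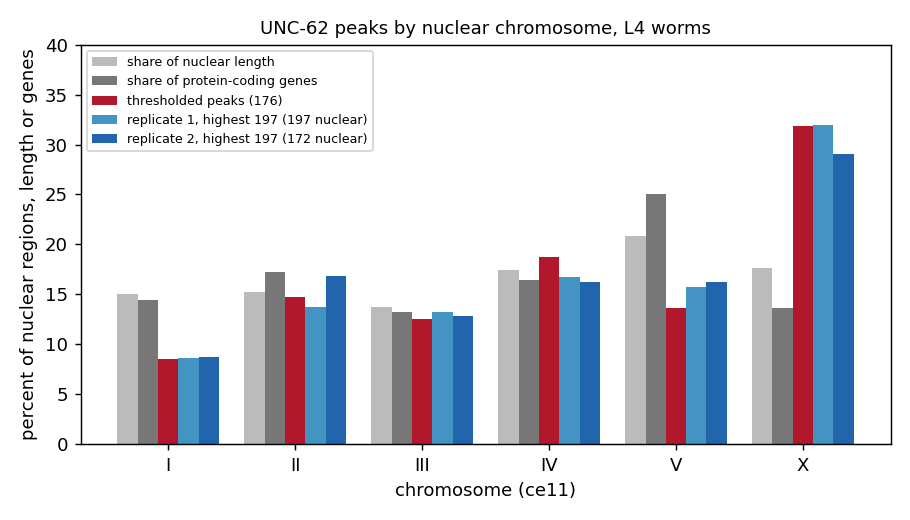
Percent of nuclear peaks on each chromosome (red, thresholded peaks; blue, the highest regions of each replicate) beside each chromosome's percent of nuclear length and of protein-coding genes (grey). X holds 31.8% of the thresholded peaks and 17.7% of the length.

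Peaks lay at promoters and near non-coding RNA genes of several classes more often than placed peaks, and in coding sequence less often. Summits lay in promoters for 95 of 197 peaks (48.2%, interval 41.3 to 55.2), against 36.8% by random placement (permutation p = 0.002, the smallest obtainable). For nuclear peaks the share was 43.8% against 30.99% (permutation p = 0.002). Coding exons held 8 summits (4.06% against 15.5%, adjusted permutation p = 0.00699). Introns held 34 (17.3% against 21.4%, adjusted permutation p = 0.203) and intergenic DNA 56 (28.4% against 23.2%, adjusted permutation p = 0.159), neither past the threshold. No summit was in a 3′ UTR (2.10% by chance, adjusted permutation p = 0.0839) or a 5′ UTR outside a promoter (0.220%, adjusted permutation p = 1), and 4 were in non-coding RNA genes (2.03% against 0.739%, adjusted permutation p = 0.159). Among the 99 peaks with signal at or above the median, 80 of them nuclear, the promoter share was 45.5% against 41.2% (permutation p = 0.41) and no longer past the threshold. The rest of the 99 were mitochondrial, and the share was not computed for the nuclear ones alone. Of the 20 highest nuclear peaks, 5 lay in promoters, against 77 of all 176. The promoter excess was thus not shown for the strongest nuclear peaks.

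Of the small RNA classes, snoRNA genes lay within 500 bp of 7 summits (3.55% against 0.319%), miRNA genes of 4 (2.03% against 0.254%) and snRNA genes of 3 (1.52% against 0.0964%), each with adjusted permutation p = 0.00333. The classes overlap, since 2 of the 4 miRNA-gene summits also lay near a snoRNA gene and the other 2 were neighbouring peaks in F09A5.3, a gene named after its values were seen. Genes annotated only as ncRNA, outside the 5 classes, lay within 500 bp of 39 summits (19.8% against 6.77%, unadjusted permutation p = 0.002). Within 100 bp there was no miRNA gene at any summit, and among the 99 stronger peaks none of these 3 classes passed (adjusted permutation p = 0.165 for snoRNA and miRNA genes and 0.273 for snRNA genes). On the highest regions of replicate 1, miRNA genes did not pass (adjusted permutation p = 0.0566) and snoRNA genes lay near 4 summits (2.03%, adjusted permutation p = 0.03). tRNA genes (17 summits, 8.63% against 7.86%, adjusted permutation p = 0.787) and rRNA genes (5 summits, 2.54% against 2.91%, adjusted permutation p = 0.929) did not differ from placement in this test, and 3 of the tRNA-gene summits and 0 of the rRNA-gene summits were nuclear.

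The Meis-class word TGACAG was the fixed question for sequence, and it lay near nuclear summits more often than near matched positions. It occurred within 100 bp of 47 of 197 summits (23.9%, interval 18.4 to 30.3), against 7.36% of matched windows (odds ratio 3.94, Fisher's exact test, adjusted p = 8.51e-11). All 47 were nuclear (26.7% of 176, against 6.82%, odds ratio 4.98), and none of the 21 mitochondrial peaks had it. The word occurred at 1.36 per kb in the 50 bp below nuclear summits in coordinate and at 2.50 per kb in the 50 bp above, against 0.367 per kb over the nuclear genome. By rank in the pooled list, TGACAG was present in 27.5% of the 200 highest nuclear regions (interval 21.8 to 34.1), 16% of the next 200, and 8% of those ranked 1001 to 2000.

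**Figure D3:**
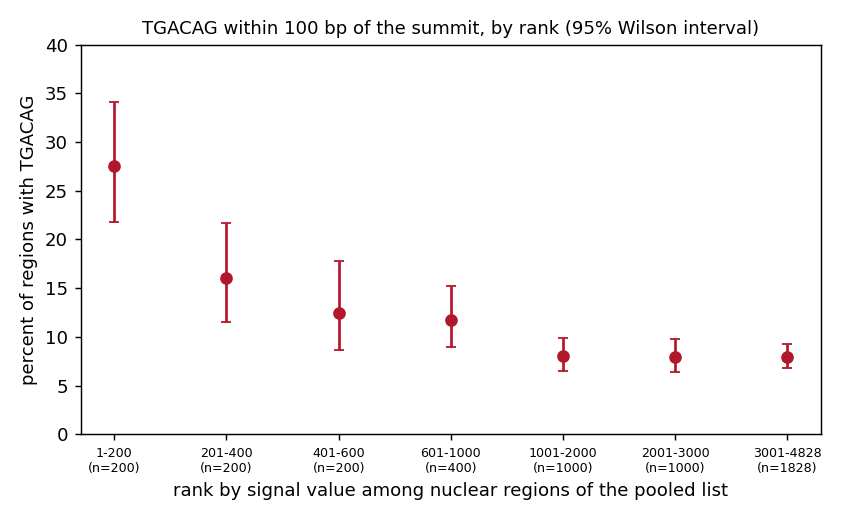
Percent of nuclear regions of the pooled list with TGACAG within 100 bp of the summit (vertical axis), in groups by signal rank (horizontal axis, number of regions in parentheses), with 95% Wilson intervals. The share falls from 27.5% at ranks 1 to 200 to 8% at ranks 1001 to 2000.

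Other words differed as well, the controls among them. The GATA-factor word, bound in worms by regulators such as ELT-2 in the intestine, was in 57.9% of summits against 33.3% of windows (odds ratio 2.75, adjusted exact p = 8.51e-11), and TGACA was in 58.4% against 33.4% (odds ratio 2.80, adjusted exact p = 8.51e-11). GAGAGAG was in 13.2% against 4.62% (adjusted exact p = 1.95e-05), CACGTG in 10.2% against 4.52% (adjusted exact p = 0.00241), GGGCGG in 10.2% against 4.31% (adjusted exact p = 0.00212) and the Pbx-Meis composite TGATTGACA in 4 peaks (2.03% against 0.406%, adjusted exact p = 0.0203). Some of these calls ended under alternatives. Among the 99 stronger peaks CACGTG (adjusted exact p = 0.0764) and GGGCGG (adjusted exact p = 0.208) did not pass, nor did GGGCGG within 50 bp (adjusted exact p = 0.0548) or TGATTGACA against flanking windows (adjusted exact p = 0.0614). The Hox-Pbx word TGATNNAT did not pass (12.7% against 14.4%, adjusted exact p = 0.593). Of the control words, GACAGT was higher in peaks (14.2% against 6.80%, odds ratio 2.27, adjusted exact p = 0.00107) and TTTCAGA lower (6.09% against 13.4%, odds ratio 0.419, adjusted exact p = 0.00289), so these windows differed from peaks in more than the words of interest. TTTCAGA did not pass on nuclear peaks (adjusted exact p = 0.0513), on the highest regions of replicate 1 (adjusted exact p = 0.0921) or within 50 bp (adjusted exact p = 0.12), and GACAGT did not pass against flanking windows (adjusted exact p = 0.0517). GACAGT overlaps TGACAGT. Where it was not part of that longer word, it was in 8.52% of nuclear summits against 4.49% of windows (odds ratio 1.98, unadjusted exact p = 0.0257).

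**Figure D4:**
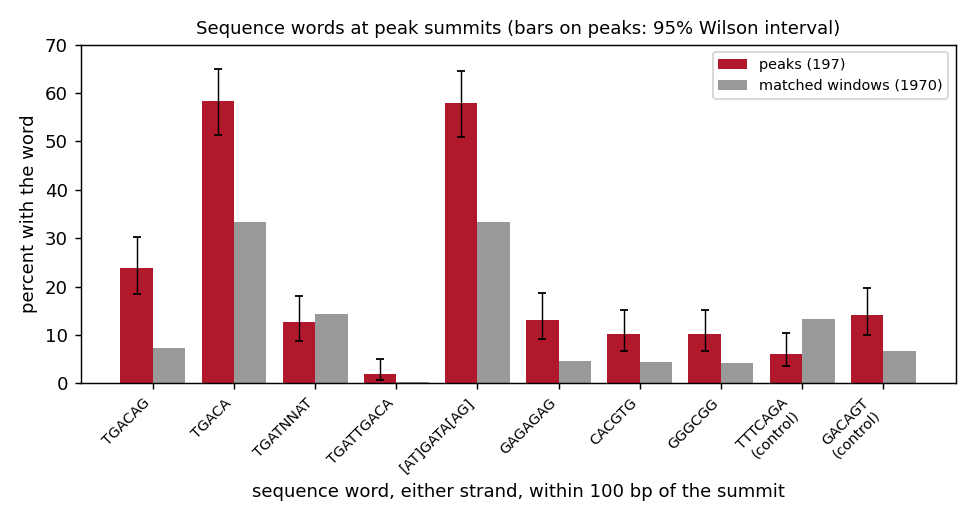
Percent of the 197 thresholded peaks (red, with 95% Wilson intervals) and of 1970 windows matched on GC content and promoter class (grey) that contain each word within 100 bp of the summit. TGACAG is at 23.9% against 7.36%, and both control words also differ between peaks and windows.

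Among genes with a peak at the promoter, the cytosolic ribosomal protein list and the heat shock and stress list passed the threshold among the 19 lists, though not under every alternative. Cytosolic ribosomal protein genes had 4 of 81 members (0.409 by chance, adjusted exact p = 0.00721, Fisher's exact test). The peaks at rpl-3 (III, signal 32.9, summit 294 bp upstream), rpl-15 (IV, 27.3, 395 bp), rpl-12 (IV, 22.0, 47 bp) and rpl-20 (IV, 21.1, 270 bp) ranked 110, 277, 113 and 479 in replicate 1. The heat shock and stress list had 3 of 29 (0.147 by chance, adjusted exact p = 0.00721). These were hsp-90 (V, signal 27.7), hsp-1 (IV, 23.3) and hsp-3 (X, 20.96), which encode chaperones of the HSP90 and HSP70 families. Promoter windows overlap, and the summits at hsp-90 and rpl-20 lay nearer to the starts of C47E8.4 (301 bp) and Y17G9B.5 (192 bp), genes named after their values were seen. Of these 7 peaks, 0 contained TGACAG. The peak at hsp-3 ranked 88 in replicate 2 and 11085 in replicate 1. With the 197 highest regions of replicate 1 in place of the thresholded peaks, 2 ribosomal protein genes (adjusted exact p = 0.55) and 1 heat shock gene (adjusted exact p = 0.639) had a promoter region, and neither list passed. With those of replicate 2, both passed (adjusted exact p = 0.00804 each). Among the 99 stronger peaks neither did (adjusted exact p = 0.273 for ribosomal protein and 0.602 for heat shock genes), and with assignment to the nearest start the ribosomal list did not (adjusted exact p = 0.28). The heat shock list passed there with daf-16, hsp-1 and hsp-3, without hsp-90 (adjusted exact p = 0.0328).

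Genes of the other lists had few or no thresholded promoter peaks. The histone list had 1 of 72, at his-37 (V, signal 26.0, 44 bp upstream, adjusted exact p = 1). The vitellogenin, Hox, TALE homeodomain, Wnt pathway, heterochronic, cuticle collagen, major sperm protein, intestine, epidermis and seam, body wall muscle, pharynx, pan-neuronal, neuronal transcription factor, germline, vulva and gonad patterning, and transgene-borne lists had 0, each with adjusted exact p = 1. Chance gave fewer than 1 gene in each of these lists, so depletion was not detectable. The heterochronic list includes the miRNA genes lin-4, let-7, mir-48, mir-84 and mir-241 and was set against all 46926 annotated genes. Among the 1000 highest nuclear regions, a set chosen after seeing the data, 9 ribosomal protein genes (2.30 by chance, adjusted exact p = 0.00456) and 6 of 29 intestine genes had a promoter region (0.824 by chance, adjusted exact p = 0.00265). The heat shock list had 3 of 29 there and did not pass (adjusted exact p = 0.229). The intestinal genes, named after their values were seen, were dod-6, fat-6, a fatty acid desaturase gene, the protease genes cpr-1 and cpr-6, act-5, an actin of the intestinal brush border, and elt-2, the GATA factor of the intestine. Their regions ranked 221, 270, 361, 629, 362 and 456 by signal in the pooled list. Only 352 regions of that list had a q-value of 0.05 or less. Most of the 1000 regions were therefore above that q-value, and a promoter region there does not by itself show binding. None of the 176 collagen genes had a promoter region in this set (5.002 by chance, adjusted exact p = 0.0678).

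None of the 10 genes named whatever their value had a thresholded peak in the gene or within 20000 bp. For unc-62 itself (V, 4497461 to 4511449) the ce11 lists of the replicates, the pool and the thresholded peaks held no region in the gene or within 1000 bp, and the best pooled region within 20000 bp ranked 4641 (q = 0.947). For unc-119 it ranked 2066. The strain carries added copies of both genes, so the copy number there is open. For the Pbx-class genes, ceh-20 had a best pooled rank of 1243 within 20000 bp and ceh-40 had no pooled region. At some of these genes the best region of a single replicate's list had a q-value under 0.05. The best of all regions in the window was taken, separately for each replicate. No chance expectation was computed for such windows, and replicate 1 listed 1521 regions with a q-value of 0.05 or less, so these values do not show binding at these genes. For egl-5, the best region within 1000 bp had q = 0.0205 in replicate 1 (summit 7814579). Replicate 2 had another best region (summit 7816427), with q = 0.911. Within 20000 bp, the best q-values in replicates 1 and 2 were 0.00648 and 0.216 for mab-5, 0.0363 and 0.161 for lin-39, 0.394 and 0.0207 for ceh-13, and 0.0355 and 0.188 for vit-2. In each of these pairs the regions had different summits, so the values do not compare the same region between replicates. In the pooled list, lin-39 had a region within the gene or 1000 bp of it, at rank 4047, and the best ranks within 20000 bp were 1686 for mab-5, 4586 for egl-5 and 503 for ceh-13. For vit-2 and vit-5, which encode yolk proteins, they were 2368 and 1167.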

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

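The test of this result was chosen only after the thresholded peaks had been seen. The pooled list held 155 nuclear regions with a q-value of 0.05 or less outside the thresholded list, on which the comparisons rest. Only the comparisons of the thresholded peaks leave these regions aside. All nuclear regions of the pooled list were counted in the shares of TGACAG by signal rank, where 16% of those ranked 201 to 400 had the word. The result below therefore overlaps with those shares and is not a separate line of evidence. TGACAG was within 100 bp of the summit in 32 of the 155 regions (20.6%), against 7.94% of matched windows (odds ratio 3.02, Fisher's exact test, p = 2.73e-06). The windows were matched as for the thresholded peaks, for which control words also differed.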

How the results depend on the processing

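The peak sets limited to nuclear peaks and to the 1000 highest nuclear regions were chosen only after the data had been seen, and the other alternatives were planned. In all, 338 alternative values of 48 results were computed, of which 51 that answer a comparison and 224 others stayed the same. That means they kept their direction and their side of the threshold. Counts had only to stay within a set factor of the main value, and ce10 overlap shares within its interval. A further 1 and 18 kept their direction and lost their call, and 6 others gained one. Another 3 and 28 reversed direction, and 7 counts that answer a comparison moved out of the set range. Calls were lost by the promoter share (stronger peaks, with signal at or above the median, permutation p = 0.41), the ribosomal list (stronger peaks, regions of replicate 1, nearest start), the heat shock list (stronger peaks, regions of replicate 1, the 1000 regions), the snRNA, snoRNA and miRNA classes (stronger peaks), miRNA genes also on regions of replicate 1 (adjusted permutation p = 0.0566), and CACGTG, GGGCGG, TGATTGACA and the control words in some settings. Calls were gained by intergenic DNA among stronger peaks, introns on regions of replicate 2, non-coding RNA genes on regions of replicate 1, and introns, non-coding RNA genes and tRNA genes in the 1000 regions. TGACAG kept both in every alternative run (odds ratio 2.44 to 5.31), as did the share on X (25.1% to 37.5%). Among peaks with signal at or above the median there were 99 peaks, the promoter share was 45.5%, TGATNNAT had an odds ratio of 1.02, 45 genes were bound, 0 lists were called (neither ribosomal nor heat shock) and the histone list had 0 members, with fewer peaks tested by construction. With the 1000 highest nuclear regions, TGATNNAT was at 1.07, 568 genes had a promoter region, and 5′ UTRs held 0.4%, 3′ UTRs 3.0% and intergenic DNA 24.7%. In that set the intestine list had 6 members, the Wnt and pan-neuronal lists 2 each, and the vitellogenin, TALE, heterochronic, epidermis, neuronal transcription factor, vulva and histone lists 1 each. With the nearest start, 165 genes were assigned, 1 list (heat shock) was called, and the intestine, neuronal transcription factor and vulva lists had 1 member each, as the latter 2 lists did with the window from 2000 bp upstream. Within 100 bp, 0 summits had a miRNA gene. With either replicate's highest regions in place of the thresholded peaks, TGATNNAT ranged from 0.957 to 1.02, lists called from 0 (regions of replicate 1) to 2, 5′ UTRs were at 0.508% in both, tRNA genes ranged from 1.52% to 9.14%, rRNA genes from 0% to 4.06%, intestine members from 0 to 2, and histone, Wnt and vulva members from 0 to 1. Of the 3 and 28 reversals of direction, 2 involved a called value (intestine and miRNA genes) and 29 did not. The cause of the changes in this section, including those in the smaller peak set, was not tested. No paired analysis was possible because the samples form a single group. Depth is unknown, so what it limits could not be assessed.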

Other observations

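The tests of replicate 2, of TGACAG in mitochondrial peaks, of word density and of a common odds factor on X, of TGACAG and of the replicate ratio in the ribosomal protein and heat shock peaks, and of transcription factor families were chosen only after the results had been seen, and the others before. Gene density was fixed beforehand as an expectation for X and was read as an explanation only afterwards. The samples form a single group, so no biological difference between groups was tested.

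Mitochondrial regions headed the thresholded list. The tables argue against binding at TGACAG as the source of these peaks. The word occurs 1 time in the 13794 bp of mitochondrial DNA, and not within 100 bp of any mitochondrial peak summit. It was in 0 of 21 mitochondrial and 47 of 176 nuclear peaks (Fisher's exact test, p = 0.00485, over peaks that overlap). The scarcity of the word in mitochondrial DNA gave that contrast in advance, so the p-value adds no evidence. The word was also absent from 129 nuclear peaks. Reads shared with nuclear copies were excluded only in part. Of the 21 peaks, which overlap, 0 had a nuclear match of at least 100 bp at 95% identity, which argues against long, near-identical copies. Without those limits on length and identity, 3 of the 21 peaks had a nuclear match. The cut-off does not cover reads shared through shorter matches, so that possibility stays open. An excess of mitochondrial signal in the replicate 2 library stays open. Of its 197 highest regions 25 were mitochondrial, against 0 in replicate 1 (Fisher's exact test, p = 2.64e-08), but this restates the counts that prompted the explanation, over overlapping regions of 2 single libraries, and does not test it.

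The X chromosome held more peaks than its length gives. The density of genes on X was too low to account for it (exact binomial p = 7.15e-10). Of the nuclear occurrences of TGACAG, 19.97% lie on X, below the share of all nuclear peaks (exact binomial p = 0.000207). That test included 129 peaks without the word, which its density cannot concern. Of the 47 peaks with TGACAG, 13 lay on X, a share not tested against that density. Word density therefore stays open for the peaks with the word. A uniformly higher X signal than in the control stays open. X held 23.4% of promoter peaks and 38.4% of other peaks (Fisher's exact test, p = 0.0358), and promoter peaks were not past their own expectation (14.8%, exact binomial p = 0.0519), which met the bound set beforehand for excluding it, as did the highest regions of replicate 2 (19.8% and 37.4%, Fisher's exact test, p = 0.0121, promoter binomial p = 0.211) but not those of replicate 1 (23.8% and 38.1%, promoter binomial p = 0.03). That bound was wrong, because promoters and other sequence differ in their expected X share (14.8% and 19.003%), and an exact test of a common odds factor over those expectations did not exclude one (p = 0.251 for the thresholded peaks, 0.276 for replicate 1 and 0.127 for replicate 2), although the factor taken from other peaks of replicate 2 would give 30.7% in promoters, above the interval of 12.5% to 29.7%.

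Ribosomal protein and heat shock genes together had 7 thresholded promoter peaks, 0 of them with TGACAG (Fisher's exact test against other nuclear peaks, p = 0.192). Whether signal at promoters without the word contributes was not decided. TGACAG was in 24.7% of promoter peaks and 28.3% of other nuclear peaks (Fisher's exact test, p = 0.611), a difference too small for these counts to decide. By the criterion set beforehand this outcome counted against the explanation, but these counts cannot exclude a small difference. A larger part of replicate 2 stays open as well, with a median log2 ratio of replicate 2 to replicate 1 of 0.92 in these 7 peaks and 0.50 in 165 others (permutation p = 0.232).

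Transcription factor genes were seen near thresholded peaks, but not beyond chance, with 7 genes of 16 families (464 genes) against 3.55 expected (Fisher's exact test, p = 0.0935) and 4.38 by random placement (permutation p = 0.299). The families were then tested near pooled regions ranked below the thresholded peaks, up to 1000. Of the family genes, 27 were the nearest gene to such a region, against 15.1 by chance (odds ratio 1.87, Fisher's exact test, p = 0.00335). The largest group among the 27 was the nhr family. Others were elt-2, ceh-60, hlh-30 and crh-1, named after their values were seen. Random placements of the regions gave 19.2 on average and up to 33 (permutation p = 0.0896), so the amount of sequence nearest to such genes may account for the count of 27. An earlier form of this test also held 11 single genes that had been picked after the genes near peaks were seen, and did not leave out genes near thresholded peaks (35 genes, odds ratio 2.25, exact p = 3.79e-05), and it is not evidence for the hypothesis.

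Whether GATA words and TGACAG tend to occur in the same peaks was not decided. GATA words were in 34 of 47 nuclear peaks with TGACAG (72.3%) and 72 of 129 without (55.8%), and the difference did not pass the threshold (Fisher's exact test, p = 0.0561). By the criterion set beforehand this outcome counted against such a tendency, but it does not exclude one.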
